A study of Mus musculus with 2 samples.

How the data were processed

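H3K4me2 ChIP-seq was carried out on hearts of newborn mice (postnatal day 0) in 2 biological replicates, each a pool of animals of both sexes, per the labels, with fragments of 300 to 500 bp. The deposited files held peak lists in narrowPeak format on the mouse genome build mm10, per the notes deposited with the samples. Peaks were called on replicate 1 alone, on replicate 2 alone and on both together (the pooled list), and a further list held the replicated peaks. Per the deposited notes, each call used the alignments and a further file for each replicate, and the same files entered tracks of fold change over control, so the further file was taken to be the control. Every one of the 40977 replicated peaks on the main chromosomes was found, unchanged, in the pooled list. The aligner, the peak caller and their versions are not given in the sources used here, nor is the rule by which a peak counted as replicated. The labels name a possible control experiment, which was not analysed here, as were no alignments or signal tracks.

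Each peak carried 3 values that the authors computed. The signal value is a ratio, by the usual meaning of the format a fold enrichment over the control, and its scale is not stated in the deposited notes. The other values deposited with each peak were −log10 of the p-value and −log10 of the q-value of the peak caller. The smallest −log10 p was 2.01 in replicate 1 and 2.23 in replicate 2, and 91.7% and 92.5% of the peaks had a q of at most 0.01. These are the authors' own values per peak, and they were used to describe, rank or filter peaks within a list and, across peaks, for a correlation between replicates. No counts were in the peak lists, so read depth was unknown and no limit of detection could be computed from it. Intervals on shares of peaks are 95% Wilson intervals.

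Positions were compared with the GENCODE release M21 annotation and the GRCm38.p6 sequence, the build that mm10 names, using 21911 protein-coding genes with 49941 TSSs on 21 chromosomes. The 10 replicated peaks on other contigs were left out of the report. A promoter was the 1000 bp on either side of any TSS of a protein-coding gene, and a gene was marked if at least 1 bp of a peak fell there. Replicated peaks were joined over gaps of up to 1000 bp into regions, and the promoter domain of a gene was its widest region touching the promoter. Distal regions lay more than 1000 bp from every protein-coding TSS, and those within 50 kb of a gene's TSS were counted for it. Peaks were shared if they overlapped by at least 1 bp, and 100 circular shifts of the peaks along their chromosomes gave the overlap by position alone.

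The gene groups were 22 lists with 1630 members, of which 1629 were matched to the annotation, Ahsp being the exception: contractile apparatus, calcium handling and conduction, cardiac transcription factors, fatty acid oxidation, glycolysis, cell cycle, endothelium and endocardium, fibroblast, smooth muscle and pericyte, epicardium, myeloid, lymphoid, erythroid, neuron, Schwann cell and autonomic neuron, hepatocyte, skeletal muscle, lung and airway epithelium, germ line and pluripotency, Hox clusters, ribosomal proteins and olfactory receptors. Shares of marked promoters and of genes at the 500 widest regions were compared with Fisher's exact test, and median domain widths and mean numbers of distal regions with a permutation test of 100000 random groups of marked genes, all two-sided and with Benjamini-Hochberg adjustment over the lists at a threshold of 0.05. For motifs, a window of 1000 bp centred on each distal region was searched on both strands for 23 consensus sequences. It was compared by Fisher's exact test with a window of the same chromosome at least 5000 bp from any peak and matched on GC content to within 2 percentage points, and 159 windows without a match were left out. The text names the genes at the 20 widest regions, of each list up to 3 marked members with the widest domains and up to the first 3 unmarked ones, fewer for lists given by their counts, and any cardiomyocyte gene marked in 1 replicate alone, of which there were none. The lists, the motifs, this rule and the tests were fixed before the data were examined. The comparison of genes marked in 1 replicate alone was added afterwards.

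The alternatives were a q of at most 0.01, each replicate left out, all pooled peaks, promoters of 500 and 2500 bp, gaps of 0 and 3000 bp, the 1000 widest regions, distances of 20 and 100 kb, background genes matched on promoter CpG ratio in 10 bins with 10000 draws, motif controls matched on repeats to within 5 percentage points, windows of 500 bp, 10 random orders of each consensus (7 for SP/KLF), a reciprocal overlap of 50% and equal numbers of top peaks. Replicated peaks touching both replicates and a −log10 q of at least 10 were added after the data were seen. The promoter CpG ratio was measured within 500 bp of each gene's 5' end. For a gene marked at another TSS, the matching therefore does not describe the marked promoter. Scripts were tested on simulated data. Lists of 25 genes whose widths were multiplied by 2 were recovered in 98% of 50 draws, and by 1.5 in 70%, over 14868 marked genes. Of 200 unchanged lists, 3% were called in the promoter test and 6.5% in the width test. These lists were counted at an unadjusted p, on simulated values. The rates are therefore not those of the adjusted tests on the real peaks, which were not measured. A motif planted in 10% of 3000 windows was the 1 called. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and bedtools 2.31.1 were used.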

Results

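Dimethylation of lysine 4 of histone H3 (H3K4me2), a chromatin mark carried by promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in hearts of mice on the day of birth (postnatal day 0). The labels gave 1 group with 2 biological replicates. Replicate 1 came from the hearts of 15 mice and replicate 2 from a pool whose number of animals was not given, and both pools mixed males and females of the strain B6NTac;B6NCrl/Lap. The design therefore allowed a comparison of the replicates with each other and a description of which genes and sequences carried the mark. No other tissue, age or treatment was measured. The files held called peaks and no read counts, so the read depth of the libraries was unknown.

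The replicates marked largely the same places, and marked them most alike at promoters. Replicate 1 had 54148 peaks on the main chromosomes, covering 53.0 Mb, and replicate 2 had 49913, covering 44.7 Mb. Of the peaks of replicate 1, 70.8% touched a peak of replicate 2 (95% Wilson interval 70.4 to 71.2%), against a mean of 3.28% when the peaks were shifted along their chromosomes. Of the peaks of replicate 2, 86.5% touched a peak of replicate 1 (86.2 to 86.8%), against 3.67% after shifting. Promoter peaks were shared more often than other peaks, at 93.0% against 59.4% in replicate 1 and 97.8% against 79.2% in replicate 2. The peaks of replicate 1 that replicate 2 lacked were narrow and weak, with a median width of 261 bp against 908.5 bp and a median signal value of 3.32 against 10.3 for the shared ones. The intervals cover counting error only. Peaks called by the authors on both replicates together numbered 59469, and 40977 of these (68.9%) made up their list of replicated peaks, which was used for genes and sequences below. A peak of this list can be absent from the peaks of a single replicate. Of the list, 88.5% touched a peak in both replicates (97.4% at promoters and 82.3% elsewhere), and 141 peaks touched neither. Across the 36279 replicated peaks that touched a peak in both replicates, the signal values of the replicates had a Spearman correlation of 0.893. This correlation is across peaks, which are not independent replicates.

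H3K4me2 lay at the promoters of 14851 of 21911 protein-coding genes (67.8%), and 41.4% of the replicated peaks touched the 1000 bp on either side of a transcription start site (TSS), against 3.58% after shifting. The replicates marked 14885.5 ± 166 genes at the promoter (SD, n = 2). Promoter peaks were the strong ones. Their median signal value was 23.4 against 3.99 for all other peaks in replicate 1, and 19.7 against 4.28 in replicate 2. A further 28.1% of the replicated peaks lay in introns and 26.2% between genes, while 4.35% lay in exons away from promoters. Chromosome X carried 0.349 ± 0.00200 times as many peaks per Mb as the autosomes (SD, n = 2), in libraries that pooled males and females.

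All promoters of the 3 cardiomyocyte gene groups carried the mark in both replicates: 30 of 30 genes of the contractile apparatus, 26 of 26 of calcium handling and conduction, and 30 of 30 cardiac transcription factors. In the replicated list 27 of 27 genes of endothelium and endocardium, 20 of 20 of fibroblasts and 16 of 16 of smooth muscle and pericytes were marked, against 11 of 15 of the epicardium. Genes of energy metabolism and division were all marked, with 25 of 25 genes of fatty acid oxidation, 20 of 20 of glycolysis and 27 of 27 of the cell cycle. In these groups Vwf, an endothelial clotting protein, lacked a promoter peak in replicate 2 and Ucp3, a mitochondrial carrier, in replicate 1. Several groups of genes from other organs were marked less often. The mark lay at 5 of 24 hepatocyte genes, leaving out Alb (albumin), Afp (alpha-fetoprotein) and Apoa2, at 9 of 23 skeletal muscle genes, leaving out the myogenic factor Myf5, at 5 of 20 germ line and pluripotency genes, leaving out Pou5f1, Nanog and Zfp42, and at 5 of 1092 olfactory receptors. Among blood lineages it lay at 4 of 20 myeloid, 8 of 20 lymphoid and 7 of 19 erythroid genes in the replicated list. The counts were 5, 15 and 8 in replicate 1, and 1, 4 and 7 in replicate 2. Neither Hba-a1 nor Hba-a2, alpha-globin genes so alike that their reads are hard to place, had a promoter peak.

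Each group was set against all other protein-coding genes, of which about 67.7% were marked, by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 22 groups. In this test 11 groups were marked more often, 7 less often and 4 did not differ. The adjusted p was 5.62e-05 for the contractile apparatus and for the cardiac transcription factors, 0.000155 for calcium handling and conduction, 0.000102 for endothelium and for cell cycle genes, 0.000224 for fatty acid oxidation, 0.000888 for glycolysis and for fibroblasts, 0.00398 for smooth muscle and pericytes, and 4.58e-10 for ribosomal proteins (77 of 79). Among the groups marked less often it was 2.25e-05 for hepatocyte, 5.62e-05 for myeloid, 0.000224 for germ line, 0.00833 for erythroid and for skeletal muscle, and 0.0182 for lymphoid genes, and the odds ratio of olfactory receptors was 0.00185. Neuronal genes also counted among the groups marked more often (22 of 25, exact adjusted p = 0.0385), including Ascl1 and Elavl4, while Slc17a6, Neurod6 and Dcx had no promoter peak. The groups that did not differ were epicardium (11 of 15, exact adjusted p = 0.787), Schwann cells and autonomic neurons (9 of 15, adjusted p = 0.641), lung and airway epithelium (8 of 17, adjusted p = 0.0858) and the Hox clusters (28 of 39, adjusted p = 0.767). Genes are not replicates, so these p-values describe the peak lists and not the spread between animals. Against genes matched on promoter CpG content (permutation test) the calls ended for cell cycle, neuronal and ribosomal genes (adjusted p = 0.911, 0.427 and 0.0954) and for myeloid, lymphoid, erythroid, hepatocyte and skeletal muscle genes (adjusted p = 0.674, 0.802, 1, 0.0818 and 0.376), while the Hox genes became lower (71.8% against 89.7%, adjusted p = 0.00126). Without replicate 2 the calls for lymphoid genes (75% marked, exact adjusted p = 0.699) and neuronal genes (adjusted p = 0.0642) ended, and without replicate 1 that for skeletal muscle did (47.8% marked, adjusted p = 0.0831). The shares of myeloid genes (25% in replicate 1 and 5% in replicate 2) and germ line genes (25% and 15%) moved between replicates while their calls stayed.

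**Figure D1:**
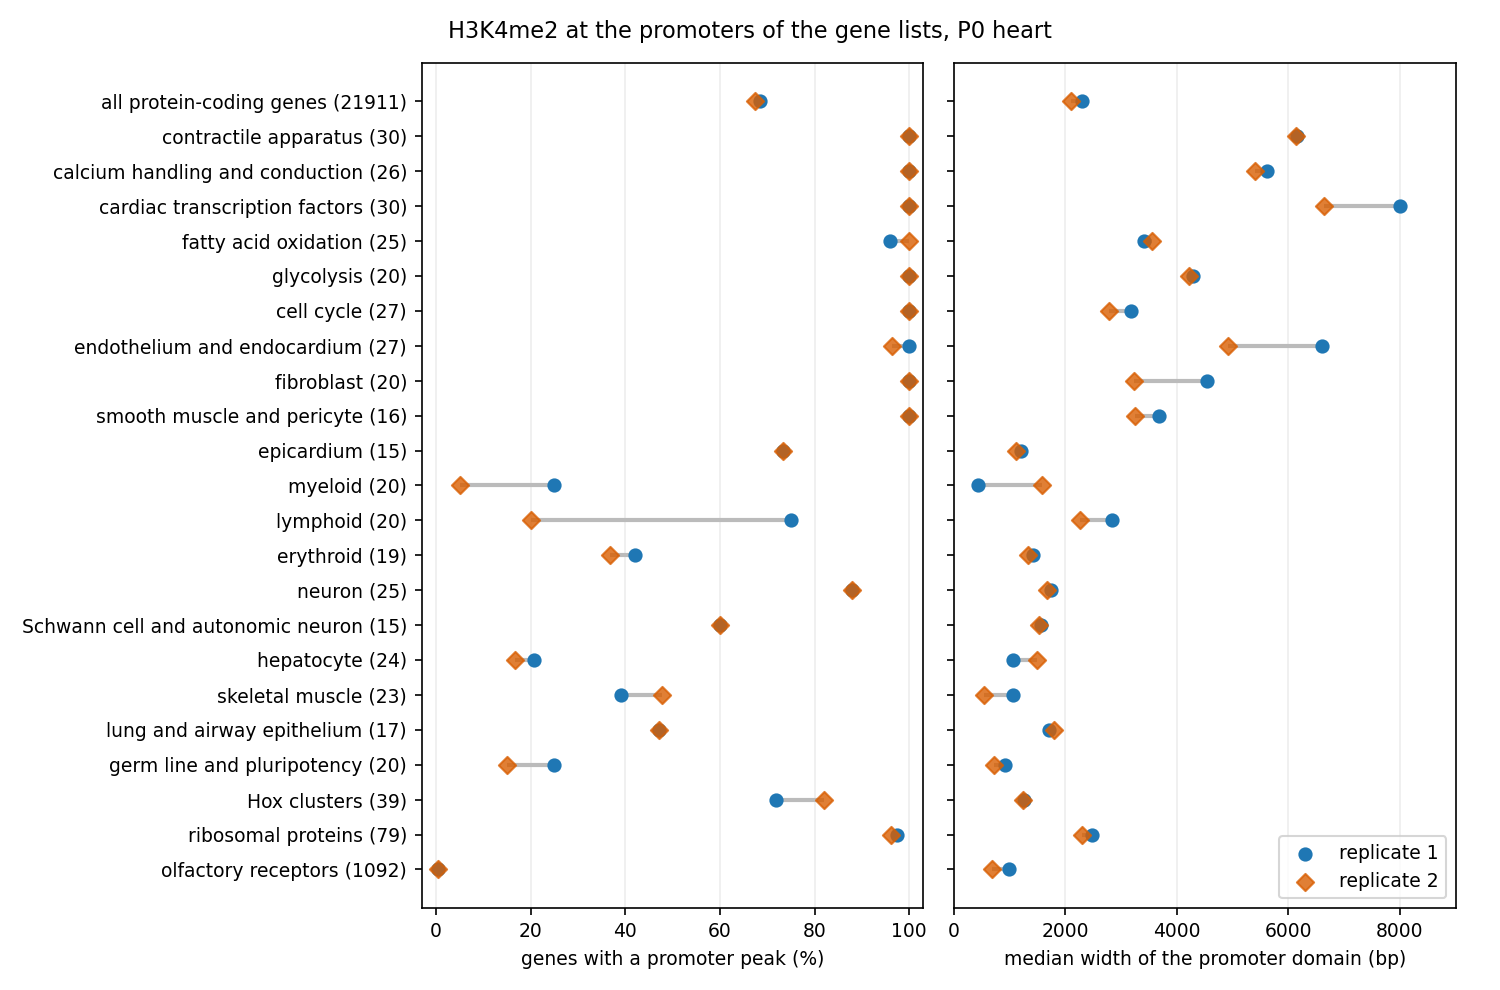
Share of each gene group with an H3K4me2 promoter peak (left, percent) and median width of its promoter domains (right, bp), with 1 point for each replicate and the number of genes in parentheses. The lymphoid group separates the replicates most, at 75% in replicate 1 and 20% in replicate 2, whereas the cardiomyocyte groups lie at 100% in both.

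The mark was broadest at the regulators of the heart. The widest region of all, 25347 bp (chromosome 8, 57311056 to 57336402, mm10), covered the whole of Hand2, a transcription factor of ventricle formation. It was followed by a 22980 bp region in Gata4 (chromosome 14, 63230098 to 63253077), a 22972 bp region over the whole of Nr2f2, a nuclear receptor of atrial identity (chromosome 7, 70347926 to 70370897), and a 21488 bp region covering 46.5% of Myh6, the alpha myosin heavy chain, and touching the promoter of Gm17428 (chromosome 14, 54955305 to 54976792). Gata6 (19858 bp) and Nkx2-5 (18772 bp, the whole gene), 2 further cardiac transcription factors, came next among the group members. Of the 20 widest regions, 8 held the promoter of a cardiac transcription factor, Meis2, Tbx20, Tbx2 and Meis1 being the others, 2 that of a contractile gene (Myh6 and Myh7) and 1 that of a calcium handling gene, Ryr2, the calcium release channel of the sarcoplasmic reticulum. The remaining ones lay at Nr2f2, Qk, Nfib, Fhl2, Bahcc1, Smad7, Cdkn1b, the pair Bcl6b and Slc16a13, and the pair Rhof and Setd1b.

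**Figure D2:**
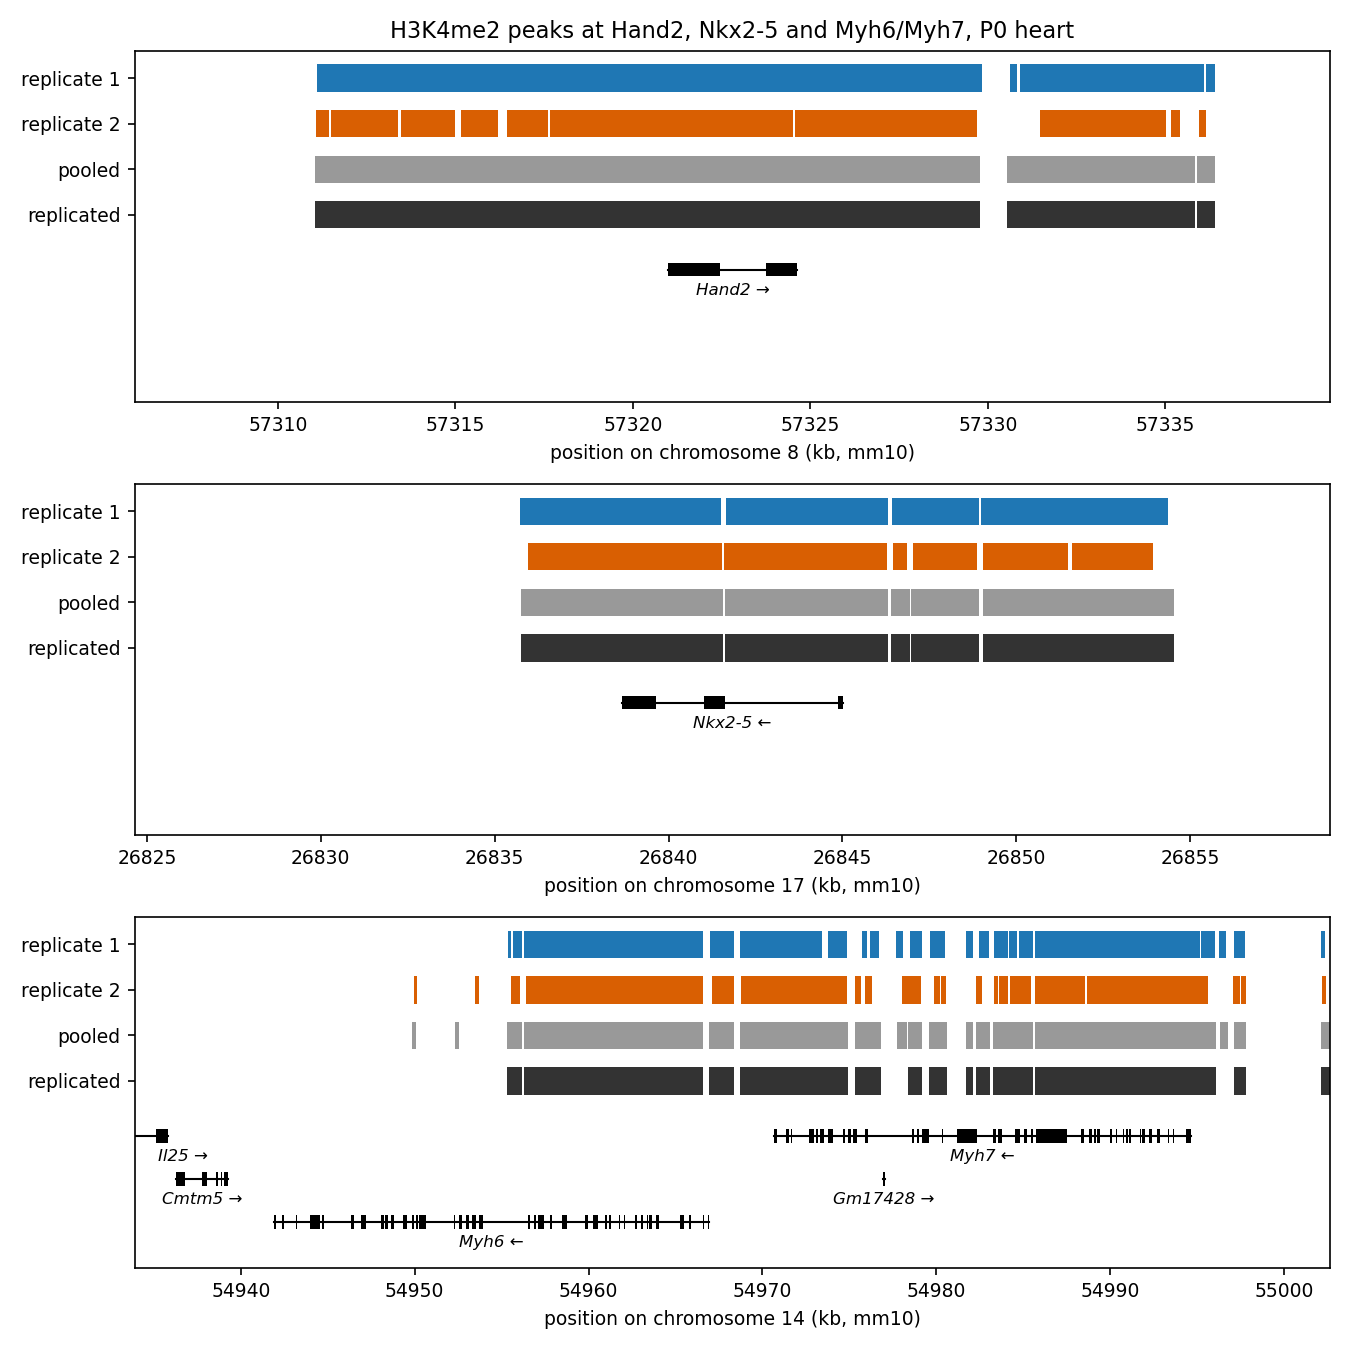
H3K4me2 peaks of replicate 1, replicate 2, the pooled list and the replicated list around Hand2, Nkx2-5 and Myh6 with Myh7, along mm10 positions in kb, with exons as black boxes and arrows giving the direction of transcription. Peaks joined over gaps of up to 1000 bp span 25347 bp at Hand2, 18772 bp at Nkx2-5 and 21488 bp at Myh6.

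Some of these widths were alike in the replicates and others were not. The Gata6 domain was 19318 ± 119 bp, that of Nkx2-5 18302.5 ± 463 bp, that of Nr2f2 22895.5 ± 187 bp and that of Meis1 14437 ± 32.5 bp (SD, n = 2). Hand2 at 21959 ± 4731 bp, Gata4 at 20555 ± 3332 bp and Myh6 at 22952 ± 3100 bp (SD, n = 2) varied more. Although its region was the widest of the replicated list, Hand2 had a lower mean over the replicates than Nr2f2 and Myh6. For 3 genes the joined width differed most, although joined peaks of both replicates covered most of the region. The domain at Qk, an RNA-binding protein, spanned 19137 bp in replicate 1 and 2164 bp in replicate 2, that at Tbx2 15650 and 6168 bp, and that at Cdkn1b, an inhibitor of cell division, 5041 and 14289 bp. Peaks of replicates 1 and 2, joined over gaps of up to 1000 bp that count as covered, spanned 99.2% and 91.3% of the region at Qk. They spanned 99.7% and 85.0% of that at Tbx2, and 91.9% and 98.6% of that at Cdkn1b.

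The same breadth ran through whole groups. The median promoter domain was 7748.5 bp for cardiac transcription factors, 6298.5 bp for the contractile apparatus, 6144 bp for endothelium and endocardium and 5964.5 bp for calcium handling and conduction, against 2317 bp for all marked genes. Glycolysis (4394 bp), fibroblast (4235.5 bp), smooth muscle and pericyte (3779.5 bp), fatty acid oxidation (3497 bp) and cell cycle genes (3258 bp) were also broader than random groups of marked genes. Leading members were Actc1, cardiac alpha actin (11287 bp), Slc8a1, the sodium-calcium exchanger (12006 bp), Atp2a2, the calcium pump of the sarcoplasmic reticulum (10689 bp), the Notch ligand Dll4 (13373 bp), Nfatc1 (11640 bp), Ppargc1a, a coactivator of mitochondrial genes (10269 bp), and the fibroblast receptor Pdgfra (9125 bp). Hadha and Hadhb, which encode the subunits of the mitochondrial trifunctional protein, lie head to head and shared 1 domain of 8857 bp. Domains were narrower than in random groups for 8 groups, among them germ line (972 bp), skeletal muscle (1038 bp), hepatocyte (1131 bp), myeloid (1153 bp) and Hox genes (1363.5 bp). Epicardial genes also fell on this side, with a median of 1246 bp over the 11 marked members, although Wt1 (10039 bp) and Tbx18 (7956 bp), transcription factors of the epicardium, had broad domains.

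In the two-sided permutation test with 100000 random groups the adjusted p was 8.8e-05 for contractile, calcium handling, cardiac transcription factor, endothelial and Hox genes, each with an unadjusted permutation p of 2e-05, the smallest it can give. The adjusted permutation p was 0.00022 for glycolysis, 0.000251 for fibroblast, 0.00492 for smooth muscle, 0.00295 for fatty acid oxidation and for epicardium, and 0.0102 for cell cycle genes. Among the narrower groups it was 0.0017 for skeletal muscle, 0.00997 for germ line, 0.0201 for hepatocyte, 0.0228 for myeloid, 0.0348 for erythroid genes (1403 bp) and 0.0102 for olfactory receptors (1000 bp). The medians for lymphoid (2139.5 bp), neuronal (1854 bp), Schwann cell (1621 bp), lung (1922.5 bp) and ribosomal protein genes (2544 bp) did not pass, with adjusted permutation p of 0.661, 0.0765, 0.0765, 0.342 and 0.213. Between replicates the median width was 7312.5 ± 966 bp for cardiac transcription factors, 6138 ± 16.3 bp for contractile genes and 5763.75 ± 1194 bp for endothelial genes, against 2195 ± 133 bp for all genes (SD, n = 2). The calls for myeloid, erythroid, hepatocyte and olfactory receptor genes ended against CpG-matched genes (adjusted permutation p = 0.195, 0.156, 0.0974 and 0.138), those for erythroid (adjusted p = 0.0778) and hepatocyte genes (adjusted p = 0.224) ended without replicate 1, and neuronal genes became narrower (1743 bp, adjusted p = 0.0431) without replicate 2. The myeloid median, which rested on 4 marked genes, was 423 bp without replicate 2 and was not tested without replicate 1, where 1 member was marked. The skeletal muscle median was 1055 bp in replicate 1 and 539 bp in replicate 2, while its call stayed in each. Without joining of peaks the erythroid call ended (adjusted permutation p = 0.0919), and neuronal (1347.5 bp, adjusted p = 0.00161) and Schwann cell genes (1332 bp, adjusted p = 0.0364) became narrower. With peaks joined over 3000 bp the erythroid median was no longer below the background (2599 against 2482 bp, adjusted permutation p = 0.861), and with peaks of −log10 q of at least 10 the skeletal muscle call ended (adjusted p = 0.0589). Among the broad groups, fibroblast genes lost the call when peaks were not joined (adjusted permutation p = 0.0919), cell cycle genes when they were joined over 3000 bp (adjusted p = 0.0566) and smooth muscle genes when only peaks with −log10 q of at least 10 were used (adjusted p = 0.154).

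The top end of the width distribution held the same heart groups. The 500 widest regions, all of at least 6319 bp, touched the promoters of 534 genes, which included 19 of 30 cardiac transcription factors (odds ratio 48.0, Fisher's exact adjusted p = 2.21e-19), 14 of 30 contractile genes (24.1, 4.81e-12), 13 of 27 endothelial genes (25.5, 1.35e-11) and 11 of 26 calcium handling genes (20.1, 3.05e-09). Fibroblast genes (5 of 20, exact adjusted p = 0.00257) and fatty acid oxidation genes (5 of 25, adjusted p = 0.00632) were also over-represented, with Vim and Sparc, a filament and a matrix protein of mesenchymal cells, among the former. Hadha and Hadhb, which share 1 domain, were counted as separate genes among the latter. No group was under-represented, and 10 of the 22 groups, the Hox clusters, neurons and hepatocytes among them, had no member there. These groups were too small for under-representation to be called. Even for the largest of them, the 28 marked Hox genes, having no member gave an unadjusted exact p of 0.625. The fibroblast call ended without replicate 2 (3 of 20, exact adjusted p = 0.103), with peaks of −log10 q of at least 10 (adjusted p = 0.0978) and with peaks joined over 0 or 3000 bp (adjusted p = 0.849 and 0.414). The call for fatty acid oxidation ended with 3000 bp (exact adjusted p = 0.0592), and glycolysis gained one with 3000 bp (4 of 20, adjusted p = 0.0318) and with the 1000 widest regions (7 of 20, adjusted p = 0.00092).

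Distal H3K4me2 regions, more than 1000 bp from every protein-coding TSS, had their highest mean counts per marked gene in the cardiomyocyte, endothelial and Hox groups. Of 34876 regions, 20233 (58.0%) were distal, with a median width of 681 bp against 2197 bp at promoters. Marked genes had a mean of 1.40 distal regions within 50 kb and unmarked genes 0.599. The mean was 2.88 for calcium handling and conduction, 2.63 for the contractile apparatus, 2.63 for cardiac transcription factors and 2.44 for endothelium and endocardium. It was highest, at 3.18, for the 28 marked Hox genes, the developmental patterning genes that lie in 4 clusters and therefore share their distal regions. These were 20 different regions, counted again for each Hox gene nearby, which a permutation of single genes does not allow for. Nkx2-5 and the endothelial factor Ets1 had 7 distal regions each, Ryr2 5 and Hand2 4. In the permutation test the adjusted p was 0.00044 for calcium handling and for Hox genes, 0.000733 for cardiac transcription factors, 0.00088 for contractile and 0.00572 for endothelial genes. The other 17 groups did not differ from random groups of marked genes, fatty acid oxidation (1.56, adjusted permutation p = 1), glycolysis (1.7, 0.969) and fibroblast genes (1.45, 1) among them. The endothelial call ended within 20 kb (0.926 regions, adjusted permutation p = 0.153), with replicated peaks that touched both replicates (adjusted p = 0.0722) and with peaks of −log10 q of at least 10 (adjusted p = 0.193). With peaks joined over 3000 bp the Hox mean was 1.57 against 1.07 (permutation p = 0.0562). The distal regions of the other groups, the cardiomyocyte groups among them, were not tested with that gap.

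The binding motifs of MEF2, GATA and TEAD were more frequent in the distal regions than in control windows. The MEF2 consensus YTAWWWWTAR, bound by muscle regulators, lay in 19.5% of 20067 windows of 1000 bp against 10.9% of windows matched on GC content (odds ratio 1.97, Fisher's exact adjusted p = 4.83e-126). The GATA consensus AGATAAG lay in 16.0% against 11.1% (1.53, 2.97e-47), the TEAD consensus RCATTCCW in 19.8% against 14.6% (1.44, 9.33e-43) and the NKX2 consensus TYAAGTGG in 6.40% against 5.63% (1.15, 0.00189). Among the called motifs, those of general regulators gave the highest odds ratios, with CTCF, an insulator protein, at 5.33 (4.19% against 0.812%, exact adjusted p = 4.58e-112), SP/KLF at 3.31 and NFI at 2.42. ETS (1.49), the E-box CAGCTG (1.36), FOX (1.32), AP-1 (1.19), RUNX (1.14) and MEIS (1.09) brought the number of enriched motifs to 13 of 23. NFY (0.644), TBX (0.824), the E-box CATCTG (0.823) and SOX (0.855) were depleted. SRF, ERR, REST, HNF4, HNF1 and OCT4-SOX2 did not differ, with exact adjusted p of 0.397, 0.359, 1, 0.983, 0.978 and 1, and the last lay in a single window. Distal windows held fewer repeat bases than their controls (14.5% against 31.7%). With controls matched on repeats as well, AP-1 (odds ratio 1.01, exact adjusted p = 0.8), SOX (0.95, 0.404) and RUNX (1.04, 0.265) lost their calls and HNF4 (0.817, 0.0228) became depleted. The MEIS call ended with replicated peaks that touched both replicates (exact adjusted p = 0.058) and with peaks of −log10 q of at least 10 (adjusted p = 0.464), and the SOX call with the former (adjusted p = 0.0588). When the letters of each consensus were put in random order, only MEF2, GATA, TEAD and RUNX of the called motifs lay above all orders tried and only NFY below them, while the odds ratios of the other called motifs, NKX2 (0.607 to 1.26), CTCF (0.95 to 17.0) and SP/KLF (1.65 to 3.32) among them, fell inside the range of their own orders. The highest order reached 1.42 for MEF2 and 1.14 for TEAD. It reached 1.49 for GATA and 1.11 for RUNX, so these 2 passed narrowly. With 10 orders each, a motif could top them all by chance.

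**Figure D3:**
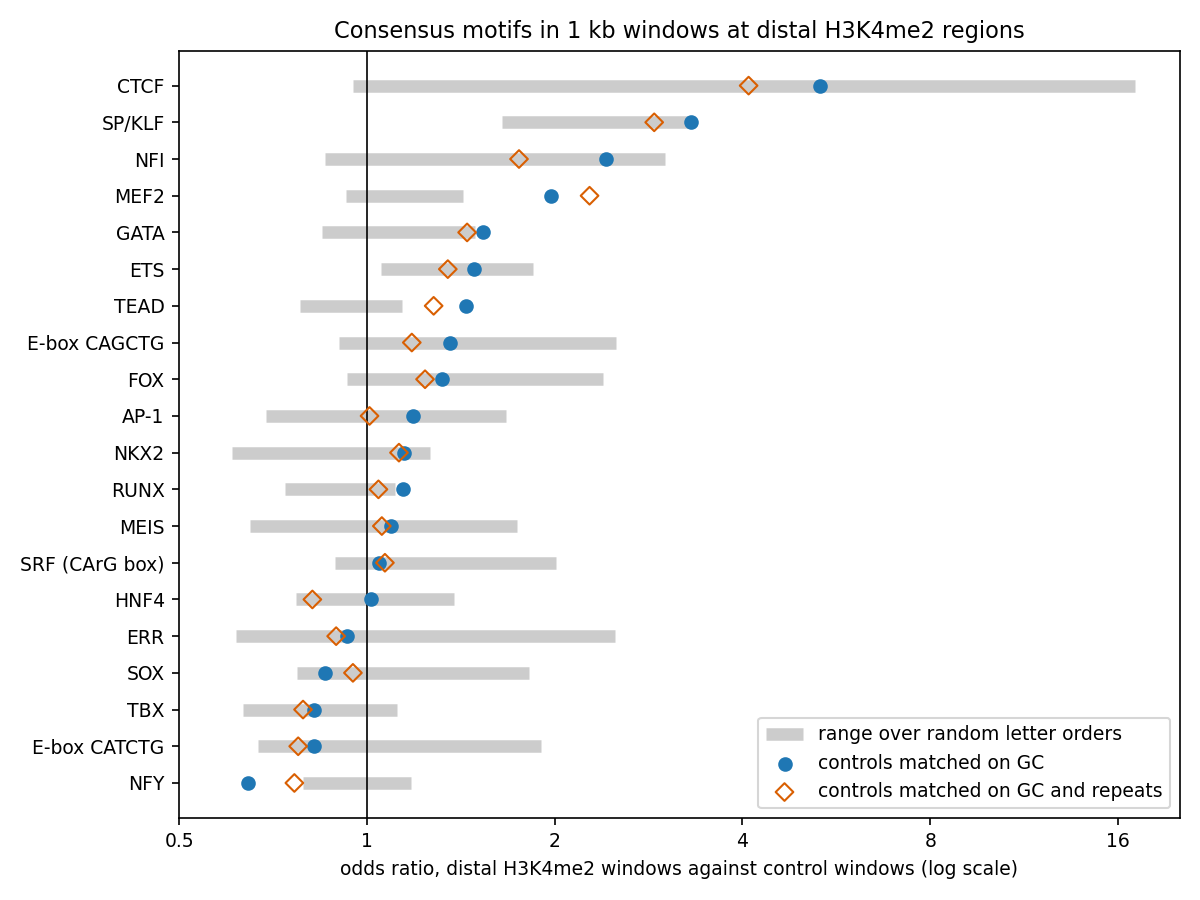
Odds ratio (log axis) of consensus matches in 1000 bp windows at distal H3K4me2 regions against control windows matched on GC content (filled circles) or on GC content and repeats (open diamonds), with grey bars for the range over random orders of each consensus; 3 motifs with few matches are left out. MEF2 (1.97), GATA (1.53) and TEAD (1.44) lie to the right of their grey bars and NFY (0.644) to the left.

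The replicates differed in which genes were marked at 2 groups of immune genes and at 2 developmental groups. Among the 20 lymphoid genes, 15 had a promoter peak in replicate 1 and 4 in replicate 2. The 11 genes marked in replicate 1 alone were chiefly T cell genes: the T cell receptor subunits Cd3d, Cd3e and Cd3g, the coreceptors Cd4 and Cd8a, the kinases Lck and Zap70, the surface proteins Cd2 and Cd5, the recombinase gene Rag1, and the B cell receptor subunit Cd79b. This share of 55% compared with 1.42% of all other genes (Fisher's exact adjusted p = 1.85e-14), and no lymphoid gene was marked in replicate 2 alone. The peaks were mostly weak, with a median signal value of 3.91 over the 11 genes in replicate 1 against 27.2 over the genes marked in both replicates, Lck (26.2) being the exception. The 310 other genes marked in replicate 1 alone were as weak, with a median signal value of 3.88. Their median promoter domain in replicate 1 was 424.5 bp, against 2838 bp for the 11 lymphoid genes. Cd3d and Cd3g shared 1 domain of 9334 bp and were counted as separate genes here and in the Fisher's exact test. At Lck and Cd4 a peak of replicate 2 touched the promoter peak of replicate 1 outside the promoter window, and at the other 9 genes none did. Around the Cd3 genes (chromosome 9, 44965572 to 45013627) replicate 1 had 17 peaks and replicate 2 had 3. Of these, the replicate 1 peak from 44964547 and the replicate 2 peaks from 44964714 and 44965674 lay at the start of the neighbouring gene Ube4a. The remaining replicate 2 peak, 44986331 to 44986515, lay in Cd3d. The myeloid genes Ptprc, Mrc1, Spi1 and Laptm5, 4 of 20, were likewise marked in replicate 1 alone (exact adjusted p = 0.00133).

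In replicate 2 alone a promoter peak was found at 3 of 23 skeletal muscle genes, the myogenic factor Myod1, the fast troponin Tnni2 and the skeletal actin Acta1 (exact adjusted p = 0.00107), and at 4 of 39 Hox genes, Hoxb1, Hoxc10, Hoxd10 and Hoxa9 (adjusted p = 0.00036). These domains were narrow in replicate 2, from 185 bp at Acta1 to 940 bp at Hoxa9. Olfactory receptors stood at 1 of 1092 among genes marked in replicate 1 alone (Fisher's exact adjusted p = 2.12e-05). As only 5 of the 1092 were marked in replicate 1 at all, this low share follows from the absence of the mark. For the other groups the adjusted Fisher's exact p was at least 0.166 in either direction. Every gene of the 3 cardiomyocyte groups was marked in both replicates. Genes marked in a single replicate numbered 321 for replicate 1 and 86 for replicate 2, beside 14682 marked in both, and the members named here were chosen after their values were seen.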

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

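The tests of the lymphoid and Hox patterns were chosen after those patterns had been seen, while the comparison of neuronal genes with CpG-matched genes was fixed before the data were examined. Of the former, the matched test of the further T-lineage genes and the test of noncoding promoters against runs of neighbouring genes were set last, after counts that enter them had been seen.

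The list of replicated peaks held 10 peaks on contigs outside the main chromosomes, which the report's comparisons did not use. They lay on 5 contigs, covered 9054 bp and reached a signal value of 21.5.

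T cell promoters carried peaks in replicate 1 that replicate 2 lacked. Of the 15 lymphoid promoters marked in replicate 1, 73.3% had no peak in replicate 2, but this list was singled out for that share. Lower sensitivity in replicate 2 as the whole cause was argued against by a list not picked for it: of 17 further T-lineage promoters marked in replicate 1, 58.8% had no peak in replicate 2, against 23.5% for genes matched on the −log10 p of the replicate 1 peak (permutation p = 0.0002, the smallest that 10000 matched draws can give). That test was set after the number of such genes was known. The same 10 genes enter the comparisons that follow, so these tests are not independent of each other. White blood cells in general, all lineages alike, were also argued against, since in lists not looked at before 10 of 22 further T-lineage genes and 1 of 21 further myeloid genes were marked in replicate 1 alone (Fisher's exact p = 0.00389). In the first lists this contrast was weaker, at 11 of 20 lymphoid and 4 of 20 myeloid genes (Fisher's exact p = 0.0484), and the myeloid genes, Ptprc, Mrc1, Spi1 and Laptm5, stood above all other genes (exact adjusted p = 0.00133), so a share of myeloid cells was not excluded. A candidate explanation that stays open is T-lineage cells in the pool of replicate 1: the further T-lineage list, with Ctla4, Cd8b1 and Cd96 among its members marked in replicate 1 alone, stood at 45.5% against 1.42% of all other genes (Fisher's exact p = 2.19e-13). These data do not separate thymus taken along with the heart from other sources of such cells, 7 of the 22 further genes were marked in both replicates, and of 12 further B cell genes 2 were marked in each replicate alone.

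Neuronal promoters were marked in heart tissue at 22 of 25 genes. CpG-rich promoters may account for this, because random genes matched on promoter CpG ratio were marked at 80%, against 88% for the neuronal genes (permutation p = 0.291). No biological explanation was tested, as the design holds no second tissue.

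The marked Hox genes had 3.18 distal regions each within 50 kb. Random runs of neighbouring marked genes averaged 1.36 (middle 95% 0.571 to 2.5, permutation p = 0.0072), below the Hox mean. The runs were not matched on the distance between genes, so they need not share distal regions as the Hox genes do. Neighbouring genes that count the same regions therefore stay open as an explanation. Promoters of noncoding genes could explain part of the excess, since without them the mean was 2.04, inside the middle 95% of such runs (0.5 to 2.29, permutation p = 0.117). Against random single genes, the test set first, 2.04 stood above 1.25 (permutation p = 0.00816), but that test leaves out that the 28 Hox genes share 20 distal regions, so this explanation stays open. Broad domains broken into several regions also stay open: with peaks joined over 3000 bp the mean was 1.57 against 1.07 in random groups (permutation p = 0.0562). No biological explanation was tested.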

How the results depend on the processing

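Replicated peaks that touch both replicates and a −log10 q of at least 10 were settings chosen after the data were seen; all other settings were fixed before. Of the list tests, 179 of 198 comparisons with the main setting kept their call for marked promoters, 179 of 195 for width, 170 of 173 for distal regions and 191 of 198 for the widest regions, and so did 188 of 207 for motifs; 7 reversed. The 3 cardiomyocyte groups kept all their calls in the settings under which each test was run. Their distal calls were not tested with peaks joined over other gaps. Whether broad domains broken into several regions add to their distal counts was therefore not tested. Width and distal comparisons with fewer than 3 marked members gave no value. Genes marked at the promoter ranged from 14565 to 15104.

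Against CpG-matched genes the lists with fewer marked promoters went from 7 to 3 and those with narrower domains from 8 to 4; without a replicate the latter ranged from 5 to 9. Marked lymphoid promoters ranged from 20% without replicate 1 to 75% without replicate 2, above the 68.5% of other genes and so on the other side from the main setting. The other results that changed direction were the marked Hox promoters against CpG-matched genes (71.8%, lower), the erythroid width with peaks joined over 3000 bp (2599 bp, no call), the HNF4 motif with controls matched on repeats (odds ratio 0.817, depleted) and the E-box CAGCTG, ETS and FOX motifs, which stood at 0.816, 0.951 and 0.996 times the median of their random letter orders (no call). With random letter orders 4 motifs were called enriched and 1 depleted, as a motif then had to lie outside the range of its own orders. With all pooled peaks the promoter calls of lymphoid, neuronal and skeletal muscle genes (exact adjusted p = 0.515, 0.0637 and 0.0554) and the width call of myeloid genes (adjusted permutation p = 0.0506) ended. A 2500 bp promoter ended the same promoter calls (exact adjusted p = 0.102, 0.0637 and 0.0553), and a 500 bp promoter that of neuronal genes (adjusted p = 0.107).

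At a −log10 q of at least 10, replicate 1 kept 27056 peaks and replicate 2 24977, of which 83.8% and 97.8% were shared; 99.9% of pooled peaks were replicated, the Spearman correlation was 0.795, promoter shares were 59.3%, 67.0% and 53.5% in replicate 1, replicate 2 and the replicated list, and X to autosome ratios 0.435, 0.458 and 0.406. At a q of at most 0.01, 74.8% of pooled peaks were replicated and the ratios of the replicates were 0.353 and 0.365. Requiring 50% reciprocal overlap left 57.5% and 62.3% of peaks shared, and 53.9% of pooled peaks were covered to 50% by each replicate. With a 2500 bp promoter the shares were 40.7%, 46.5% and 45.9%. Apart from fewer peaks at stricter thresholds and more base pairs in wider promoters, the cause was not tested. No paired analysis was possible because the study has 1 group. Unknown depth limits any statement that a promoter lacked the mark.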

Other observations

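The widest distal regions and the further groups below were picked after the values were seen, and no explanation of them was tested.

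The widest distal region, 10480 bp (chromosome 1, 74027102 to 74037581, mm10), lay in introns and exons of Tns1, a protein of focal adhesions, 53.8 kb from its nearest protein-coding TSS, and covered exons over 2.85% of its length. The second, 9823 bp (chromosome 11, 58994207 to 59004029), lay inside Obscn, a giant protein of the sarcomere, with 42.8% of its length exonic. A 7501 bp region (rank 10) lay inside Lmo7 and a 6542 bp region (rank 19) inside Ryr2, the latter 72.6 kb from the TSS. Other wide regions lay between genes, 59.5 kb from Ppara, the nuclear receptor that governs fatty acid oxidation (8912 bp), and 50.3 kb from Gata5, a cardiac transcription factor (8909 bp). The regions at Obscn and near Gata5 touched the TSS of a noncoding gene, whereas those at Tns1, Lmo7, Ryr2 and near Ppara did not. The regions of ranks 3, 4, 7, 8 and 9 (9718 to 8312 bp), not described here, all touched such a TSS. Peaks of replicates 1 and 2 covered 70.0% and 77.4% of the region at Tns1, 80.8% and 77.0% of that near Ppara, and 72.2% and 44.6% of that in Ryr2.

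Genes of other groups that were marked in 1 replicate alone included Vwf of the endothelium, Hemgn of the erythroid group, Apoa1 of the hepatocyte group, Myog of skeletal muscle, and Dppa3 and Fgf4 of the germ line group in replicate 1, and Ucp3 of fatty acid oxidation in replicate 2. At Apoa1 and Dppa3 a peak of replicate 2 touched the promoter peak of replicate 1 outside the promoter window. Genes that are marked but are regulators of other organs were also found: Foxa2 (2539 bp) and Foxa1 (2167 bp) of the lung group and Foxa3 (2452 bp) of the hepatocyte group had promoter domains close in width to the median of 2317 bp over all marked genes, in both replicates, while Sftpa1, Sftpb and Sftpc, which encode surfactant proteins of the lung, had no promoter peak.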
